A study of Homo sapiens with 4 samples.

How the data were processed

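Binding of the human transcription factors GATA1 and P53 to DNA was measured with UV-Bind, a protein binding microarray in which double-stranded DNA on a slide is exposed to ultraviolet light or left unexposed before protein is added. There were 4 arrays, 1 for each protein and condition. Per the labels, GATA1 was applied at 65 nM and P53 at 420 nM, and bound protein was read in a single colour with the dye Alexa 635. The dose of light, the way the protein was detected, the scanner, its gain and the software were not given in the sources used here.

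Each deposited file held 62976 spots in a layout that was identical in the 4 files. Of these, 54614 were universal probes, 7040 were spots of 877 designed sequences (874 with 8 spots and 3 with 16), and 1322 were control spots for which the files list no sequence. Every universal probe was 60 bases long. Positions 21 to 60 were the same in all of them and held 0 dipyrimidine steps, the first 5 bases were 1 of 4 flanks, and positions 6 to 20 carried the variable part. By their names, 43691 of the universal probes belonged to a set that covers all 9-mers and 10923 to a set that covers all 8-mers.

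Per the file headers, the authors deposited spot intensity in linear scanner units as a raw column, a normalized column and a column adjusted for position on the slide. The normalized intensity equalled the raw intensity in every row, because the deposited columns that would correct for the amount of double-stranded DNA, measured with a Cy3 dye, all held 1. Differences between probes in how much double-stranded DNA they carried therefore remain in every value. The authors' adjusted intensity was the raw intensity divided by the median intensity of the spots around it and multiplied by the median of all spots of the array, as tested on each file. The size of that neighbourhood is not given in the sources used here. No background subtraction was visible in the columns. Spots at the highest value of the scanner give only a lower bound, and there were 76 of them among the universal probes on the GATA1 array without UV, 1118 on the GATA1 array with UV, 1 on the P53 array without UV and 57 on the P53 array with UV.

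Signals from different probes are compared within an array because the affinity of a protein for different sequences is what this assay measures. The adjusted intensity was taken to the log2 scale with no pseudocount. For each protein, the UV change of a probe was log2 of the intensity with UV minus log2 of the intensity without UV, centred on its median over the universal probes. No quantile or loess normalization entered the main values, since light can shift many probes one way. A change is thus relative to the typical probe of the same 2 arrays. Probes were grouped by the 6-mers of their variable part, with reverse complements merged, which gave 2080 6-mers carried by 107 to 431 probes each. The change of a 6-mer was the median over its probes with a 95% bootstrap interval from 500 resamples of probes, and a 6-mer was counted as higher or lower when the median was at least 0.3 in size and the interval excluded 0. Within each array, a rank score was computed as the area under the ROC curve of probes with the 6-mer against all other probes, minus 0.5, so that a score of 0.5 means that every probe with the 6-mer was brighter than every other probe. The overlap of the top 5% of 6-mers was given with a Wilson 95% interval.

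Lists of sites, 35 in all, were fixed before the data were examined, together with the comparisons, the rule for a higher or lower 6-mer and the rule for the sequences named. Site names use R for A or G, Y for C or T, W for A or T and S for C or G. A probe entered a list when its variable part held the site on either strand. Each list's median change was set among 10000 random lists of the same number of probes matched on mean log2 signal over the 2 arrays, in 100 bins. Named in the text are every list, for each array the 5 6-mers of highest rank score, for each protein the 6 largest rises and the 6 largest falls with an interval that excluded 0, and the 5 6-mers that gained and the 5 that lost most rank score. Dipyrimidine steps were counted as neighbouring bases that are both pyrimidines on one strand or the other, from 0 to 5 per 6-mer.

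With 1 array for each protein and condition there is no replicate of any difference between conditions, no p-value is given, and the condition cannot be told apart from the array. Intervals cover the spread between probes of these arrays only, 6-mers share probes and are not independent, and the spots of a designed sequence are technical repeats. The number of arrays limits the precision. Over the designed sequences, the SD between spots of one sequence on the log2 scale was 0.40 on the GATA1 array without UV, 0.14 with UV, 0.22 on the P53 array without UV and 0.12 with UV.

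The change calls were tested on simulated data made from the measured GATA1 and P53 signals without UV, with spot noise and with known changes in 15 6-mers of each size. For GATA1, 15 of 15 planted changes of -1, 15 of 15 of -0.5, 14 of 15 of 0.5 and 15 of 15 of 1 were called among 2080 6-mers. For P53, 15 of 15 were called at each of these sizes, and 0 of 22 6-mers with little overlap with the planted ones were called in either simulation. The simulation held no compression of the signal range. Alternatives changed the centring, the signal column, the size bound, the pseudocount, the length of the k-mers, the rank statistic, the probes used and the counting of steps. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The designed sequences were compared by spot only after the data had been seen, and those of the damage series were not analysed here.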

Results

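GATA1, a zinc finger factor of the red cell lineage that binds WGATAR, and P53, a tumour suppressor that binds as a tetramer to pairs of the decamer RRRCWWGYYY, were each measured on 1 array left unexposed and 1 array exposed to ultraviolet light. Light of this kind links neighbouring pyrimidines on a strand, so the arrays ask which sequences each protein prefers once DNA carries such lesions. The median raw intensity of the universal probes was 608 on the GATA1 array without UV and 23151 with UV. For P53 it was 310 without UV and 17799.5 with UV.

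Both irradiated arrays were far brighter and held less contrast between probes. The median adjusted intensity was 38.3-fold higher with UV for GATA1 and 57.4-fold higher for P53, a shift of 5.17 and 5.75 on the log2 scale. The span from the 5th to the 95th percentile of log2 intensity went from 3.98 to 1.61 for GATA1 and from 2.76 to 1.496 for P53. The scanner gain is not given in the sources used here, so the shift itself has no scale, and all changes are relative to it. Over the universal probes, the Pearson correlation of log2 intensity between the array without UV and the array with UV was 0.651 for GATA1 and 0.613 for P53.

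GATA1 kept most of its preferences on irradiated DNA. Without UV the 5 6-mers of highest rank score were AGATAA (0.491), CTTATC (0.490), CGATAA (0.488), TGATAA (0.485) and GATAAC (0.483), all with the GATA core on one strand. With UV they were GATAAC (0.471), GATATC (0.465), GCGATA (0.461), AGATAT (0.460) and the C run CCCCCC (0.455). Of the 104 6-mers that made up the top 5%, 77 were shared between the arrays (74.0%, Wilson interval 64.9 to 81.5), against 5.2 for random lists, and the GATA core was in 47 without UV and in 44 with UV. The 27 that entered the top 5% with UV included 21 with AAA or TTT. Across all 2080 6-mers, which are not independent replicates, the Spearman correlation of the rank scores was 0.696.

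With P53, the rank order of the 6-mers of the universal probes differed more between its arrays. The variable part of 15 bases is too short for a pair of decamers, so full P53 sites are not covered here. Without UV its leading 6-mers were CCCCCC (0.412), CATGTC (0.290), CCCCCA (0.266), GGGGGA (0.264) and AGGGGG (0.260). With UV, CCCCCC (0.374) was followed by AAATTT (0.358), AAAATT (0.353), TTTAAA (0.351) and AATTTC (0.346), of which AAATTT had scored -0.05 and TTTAAA -0.07 without UV. Of the top 104 6-mers, 7 were shared (6.73%, Wilson interval 3.30 to 13.2), hardly more than the 5.2 of random lists. The number with AAA or TTT went from 1 to 72, the number with CATG, the centre of the strongest P53 sites, from 15 to 3, and the number with CCCC or GGGG from 34 to 3. The Spearman correlation across 6-mers was 0.441. These scores merge reverse complements, while the P53 signal without UV correlated at -0.81 between a 6-mer and its reverse complement. The small overlap therefore holds for merged 6-mers only. The P53 signal without UV also correlated at 0.795 with pyrimidine steps and at -0.783 with purine steps of the listed strand. How far these ranks reflect a preference of P53 was not tested. With the strands kept apart, an alternative chosen after seeing the data, 32.7% of the top 5% were shared and the Spearman correlation was 0.605. With reverse complements merged, the E-score and 8-mers gave 15.4% and 16.2% shared.

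**Figure D1:**
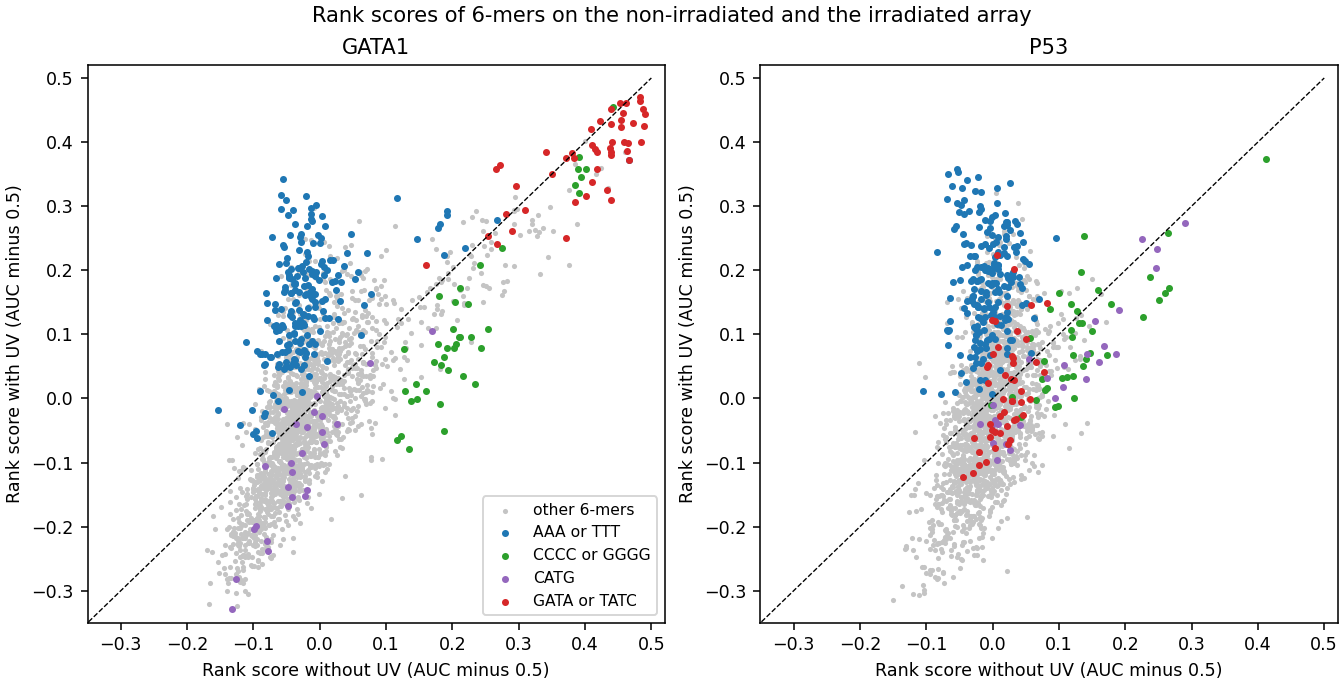
Rank score of each of 2080 6-mers without UV (horizontal axis) and with UV (vertical axis), as AUC minus 0.5, for GATA1 and P53, with reverse complements merged and colours for sequence classes. Most 6-mers with GATA stay near the dashed line of equal scores for GATA1, and 6-mers with AAA or TTT lie above it for both proteins.

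Relative to other probes, GATA1 lost most signal with UV at sequences with its own core and at runs of G or C, and gained it at runs of A or T. The 6 largest falls on the log2 scale were CTTATC (-4.33, interval -4.51 to -4.16), AGATAA (-4.15), TGATAA (-3.89), CGATAA (-3.86), GATAAC (-3.53) and GATATC (-3.44). The 6 largest rises were AAATTT (0.73, interval 0.64 to 0.87), AAAATT (0.71), AAAAAC (0.64), AAAAAA (0.63), TTTAAA (0.63) and AATTTC (0.63). In all, 136 6-mers were higher and 169 lower. The lower ones took in 44 of the 48 6-mers with the GATA core, 40 of the 40 with CCCC or GGGG and 85 others, and 97 of the 136 higher ones held AAA or TTT. By rank score the largest gains were those of AAATTT, AAAATT, TTTAAA, AAATTC and AAAAAA, up by 0.40, 0.38, 0.36, 0.35 and 0.34. The largest losses were those of GGGGCA (-0.24), CGGGGC (-0.21), CCCGCA (-0.21), CAGGGG (-0.21) and GCCCGC (-0.20). As the residual of a linear fit of the 2 arrays' log2 signals, 3.99% of 6-mers were higher and 2.88% lower, against 6.54% and 8.12% here, and the falls of GATAAC and GATATC turned into values of 0.13 and 0.0151. A pseudocount left 1.25% higher and 6.44% lower. CCCCCC, at -1.43 here, was at 0.53 as the residual and at 0.81 with quantile normalization.

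The GATA consensus stood far above the typical probe on the GATA1 array without UV, and above it by less on the array with UV. Probes with WGATAR had a median signal 17.8-fold above the array's median without UV and 1.76-fold above it with UV, a change of -3.14 on the log2 scale (interval -3.26 to -3.05, 938 probes). The members fell in the order of their signal without UV, with AGATAA at -4.15, TGATAA at -3.89, AGATAG at -2.41 and TGATAG at -2.02, and the GATA core outside the consensus fell by 1.38. Variants of the core fell by less than WGATAR, with WGATTR at -1.49, WGATCR at -0.68 and WGATGR at -0.22, and WGACAR was at -0.02 with an interval that held 0. The rank score of WGATAR went from 0.474 to 0.393, that of TGATAG from 0.439 to 0.310, and that of the GATA core outside the consensus from 0.403 to 0.394. In scanner units the median excess of WGATAR over the array's median did not fall, at 10344 without UV and 17749 with UV. For the GATA core outside the consensus it was 2522 and 17117. With the gain not given, these units cannot be set on one scale between arrays.

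The size of these falls depended on how the narrower signal range with UV was treated. With quantile normalization the change of WGATAR was -0.996, and as the residual of a linear fit -0.21. The GATA core outside the consensus was at 7.56e-05 and 0.207 under these alternatives. As residuals AGATAG (0.02), WGATTR (0.0351) and WGATCR (0.0479) changed direction too, while with quantile normalization they were at -0.47, -0.39 and -0.28. Random lists matched to WGATAR on mean signal had a median change of -2.80, but 92.6% of the probes they were drawn from held GAT followed by a base, so they compare GATA1 sites with each other. On the UV array, 18.1% of the WGATAR probes were at the highest scanner value.

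Relative to other probes, P53 gained signal with UV at runs of A or T and lost it at runs of C and at its own core. The 6 largest rises were GAAAAA (0.83, interval 0.67 to 0.97), AAAAAT (0.79), TTTAAA (0.76), AAAAAA (0.75), AAAATT (0.74) and AAATTT (0.73). The 6 largest falls were CCCCCC (-1.28, interval -1.43 to -1.05), CATGTC (-0.62), CCCCCA (-0.59), CATGCC (-0.58), ACCCCC (-0.55) and AGGGGG (-0.54). In all, 174 6-mers were higher, 112 of them with AAA or TTT, and 63 were lower, among them 10 of the 26 6-mers with CATG and 14 of the 40 with CCCC or GGGG, while 39 of the 63 held none of GATA, CATG and these runs. By rank score TTTAAA, AAATTT, AAAATT, TTAAAA and AAAAAA gained most, up by 0.419, 0.412, 0.405, 0.393 and 0.380. The largest losses were those of CTGCAG (-0.29), CTACAG (-0.24), ACTGCA (-0.24), GCTGCA (-0.22) and ACACAG (-0.22). With quantile normalization 10.5% of 6-mers were higher and 9.33% lower, against 8.37% and 3.03% here, and as the residual of a linear fit CCCCCC, CATGTC and CATGCC were at 0.11, 0.19 and 0.08. With the strands kept apart, an alternative chosen after seeing the data, 17.6% were higher and 21.8% lower. A pseudocount left 2.12% higher and 0.721% lower.

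P53 decamers on the universal probes, as one list, fell in log2 signal relative to other probes without a fall in rank score, while shorter forms of the site fell in both. Probes with the decamer RRRCWWGYYY changed by -0.38 (interval -0.60 to -0.10, 64 probes), and those with a CATG centre by -0.75 (interval -1.34 to -0.46, 17 probes). The rank score of the decamer was 0.224 without UV and 0.257 with UV, a difference whose interval held 0, and that of the decamer with CATG rose from 0.401 to 0.461. The decamer with a CAAG or CTTG centre, at -0.17, and the one with CTAG, at -0.36, had intervals that held 0, and the rank score of the former rose from 0.187 to 0.275. That of the CTAG form, with 15 probes, went from 0.104 to -0.013, a difference whose interval held 0. Among shorter forms RRCWWGYY fell by 0.35, RCATGY by 0.42, RCTAGY by 0.24, RCAAGY by 0.17 and CWWG outside the site by 0.03, and the rank score of RRCWWGYY went from 0.155 to 0.107 and that of RCATGY from 0.208 to 0.153. Lists matched on signal to the CATG decamer changed by -1.29, so these 17 probes lost less than others of their brightness, at percentile 99.8. The whole decamer list and its CAAG or CTTG form also lost less than their matched lists, at percentiles 97.1 and 98.3. Other P53 sites went the other way, with RCAAGY, RCTAGY and CWWG at percentile 0. RRCWWGYY at 5.25, the CTAG decamer at 5.96 and RCATGY at 10.7 lay on the same side but closer to their matched lists. With quantile normalization and as the residual of a linear fit, the decamer's change was 0.0712 and 0.29, and as residuals RRCWWGYY and RCATGY were at 0.0112 and 0.0356.

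**Figure D2:**
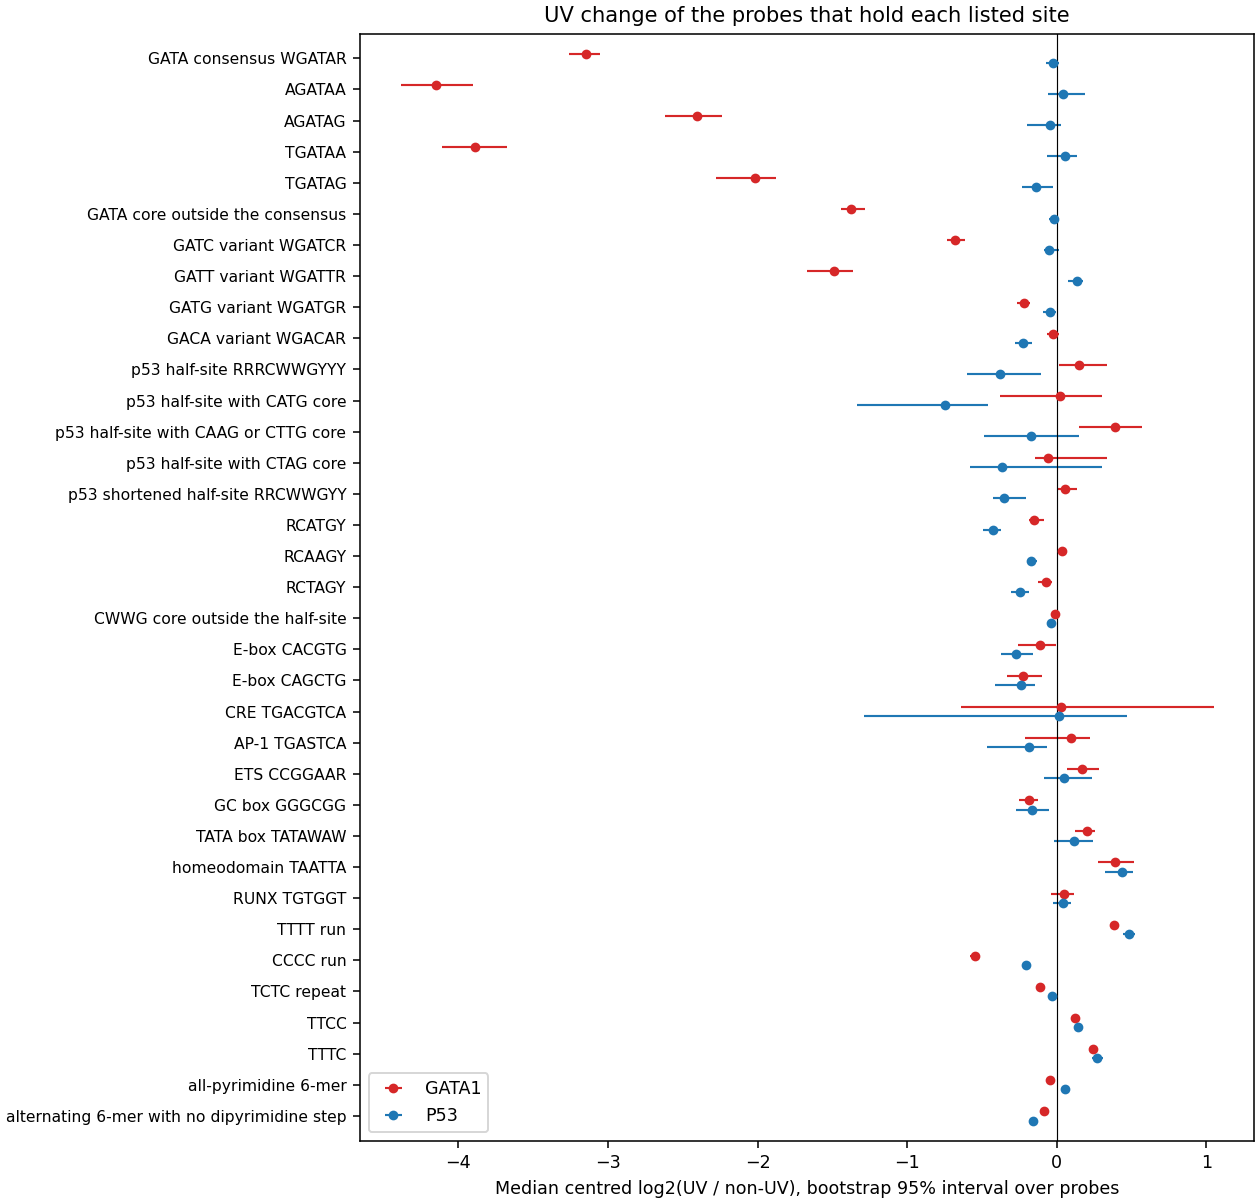
Median UV change of the probes that hold each of the 35 listed sites, for GATA1 and P53, on the log2 scale and relative to the typical probe, with the bootstrap 95% interval over probes as bars. GATA sites reach -4.15 with GATA1 and stay near 0 with P53, while the TTTT run lies above 0 with both; under quantile normalization or as the residual of a linear fit the falls of GATA sites with GATA1 are smaller or turn, and those of P53 sites with P53 shrink, turn or, as for RCTAGY, grow.

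The sites of each protein behaved differently with the other. With P53, WGATAR changed by -0.02 and AGATAA by 0.04, and of the 10 lists of GATA sites and variants 3 had an interval below 0, TGATAG at -0.14, WGATGR at -0.04 and WGACAR at -0.23, and 1 above it, WGATTR at 0.13. With GATA1, the P53 decamer changed by 0.15 (interval 0.01 to 0.33), its CAAG or CTTG form by 0.39 and RCATGY by -0.15.

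In log2 change, dipyrimidine steps went with a rise where they were made of A and T with both proteins. They went with a fall where they were made of G and C with GATA1, but not clearly with P53. By rank score, 6-mers of G and C only did not fall further with more steps, although the CCCC run lost rank score with both proteins. Among the 36 6-mers of A and T only, the median change of GATA1 went from -0.08 with 0 steps to 0.62 with 4 steps, and that of P53 from -0.11 to 0.73, with 2 and 6 6-mers in these classes. Over all 6-mers the Spearman correlation of change with the number of steps was 0.217 for GATA1 and 0.452 for P53. Within 6-mers of A and T only it was 0.928 and 0.965, and within the 36 6-mers of G and C only it was -0.44 and -0.13. The 65 6-mers with at least 3 TT steps rose by 0.43 with GATA1 and 0.52 with P53, and the 65 with at least 3 CC steps were at -0.43 and -0.14. With the number of CC steps the change correlated at -0.0326 with GATA1 and 0.0803 with P53. For 6-mers of G and C only, the change with GATA1 went from -0.10 with 0 steps to -0.45 with 4. With P53 it went from -0.12 to -0.08. Their median change in rank score rose instead, from -0.13 with 0 steps to -0.06 with 4 for GATA1, and from -0.14 to 0.01 for P53. None of the 72 6-mers with 0 steps was counted as higher with either protein. With steps counted over the whole variable part of a probe the correlations were 0.0859 and 0.171, and with only the probes brighter than the median probe that of P53 was 0.156.

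The fixed lists showed the same order. The TTTT run rose by 0.38 (interval 0.35 to 0.42) with GATA1 and by 0.48 (0.44 to 0.52) with P53, TTTC by 0.24 and 0.27, and TTCC by 0.12 and 0.14. The CCCC run fell by 0.55 and 0.20 and the TCTC repeat by 0.11 and 0.03. As the residual of a linear fit the CCCC run was at -0.0128 and 0.000215, and with quantile normalization at -0.23 and -0.12. By strand, GGGG on the listed strand was at -0.86 with GATA1 and -0.12 with P53, and CCCC there at -0.0069, with an interval that held 0, and -0.41. The all-pyrimidine 6-mer was at -0.04 with GATA1 and 0.05 with P53, and the alternating 6-mer with 0 steps fell by 0.09 and 0.16. The rank score of the TTTT run went from -0.02 to 0.216 with GATA1 and from -0.02 to 0.252 with P53. That of the CCCC run went from 0.212 to 0.0888 with GATA1 and from 0.1165 to 0.0796 with P53. With only the brighter probes, TTCC and the all-pyrimidine 6-mer were at -0.01 and -0.22 with P53.

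**Figure D3:**
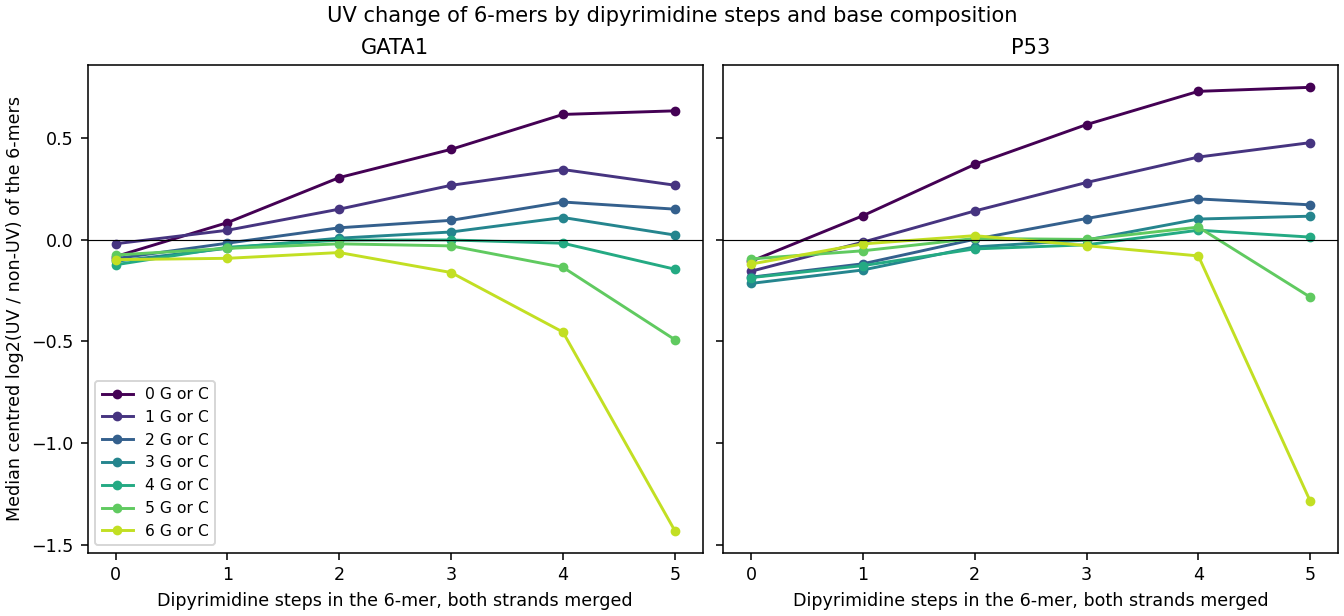
Median UV change of 6-mers (log2, relative to the typical probe) against the number of dipyrimidine steps, with a line for each number of G or C bases from 0 to 6. The line with 0 G or C climbs from -0.08 to 0.63 for GATA1 and from -0.11 to 0.75 for P53, while the line of 6 ends at the single 6-mer CCCCCC, at -1.43 and -1.28, which turns positive as the residual of a linear fit; the classes at the ends of these lines hold 1 or 2 6-mers.

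The rise at A and T runs depended on the strand that held the run, a comparison made after seeing the data. Probes with AAAA on the strand listed in the files rose by 0.74 (interval 0.71 to 0.77) with GATA1 and by 0.91 (0.88 to 0.94) with P53. Probes with TTTT on that strand were at 0.02 (interval -0.02 to 0.05) with GATA1 and fell by 0.19 with P53. Without UV the AAAA probes lay below the array's median, at -0.35 and -0.55, and the TTTT probes above it, at 0.31 and 0.65. With UV both lay above it, at 0.35 and 0.26 for GATA1 and at 0.32 and 0.38 for P53, and the rank score rose in both orientations. Across 6-mers with the strands kept apart, the P53 signal without UV correlated at -0.81 between a 6-mer and its reverse complement, and at 0.286 with UV, while for GATA1 these values were -0.13 and 0.604. The P53 change correlated at -0.59 with pyrimidine steps and at 0.803 with purine steps of the listed strand, and that of GATA1 at -0.25 and 0.436.

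**Figure D4:**
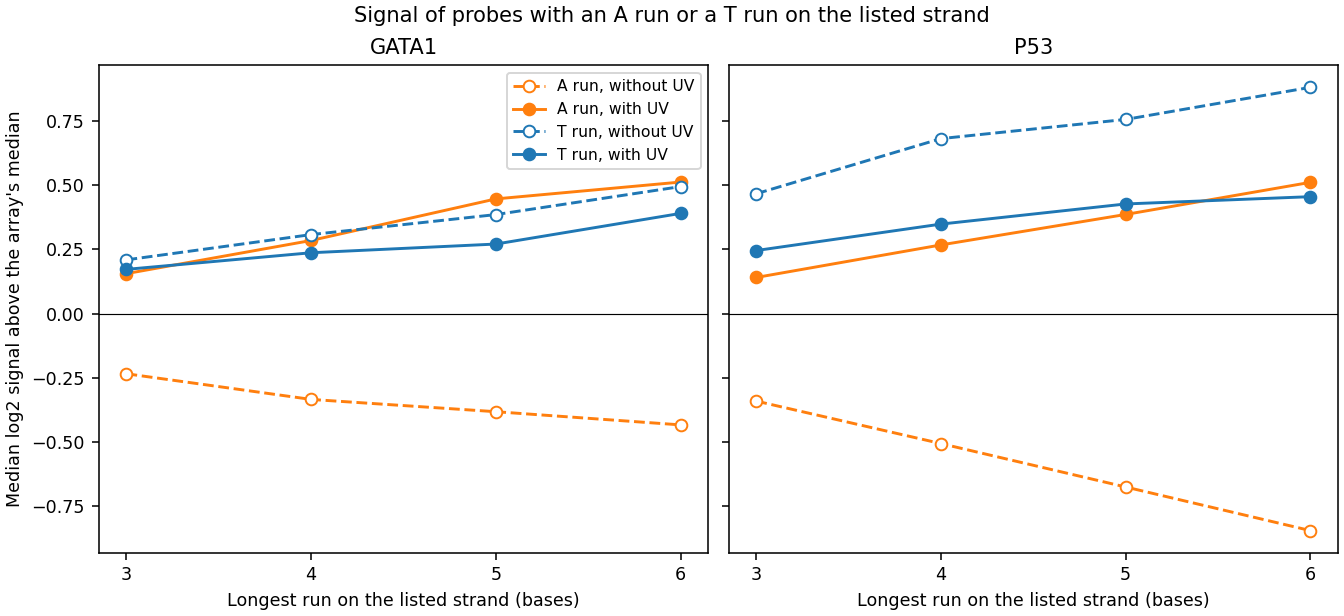
Median signal, as log2 above the array's median, of probes whose longest run on the listed strand is of A or of T, against the length of the run, without UV (open points) and with UV (filled points). A runs lie below 0 without UV, down to -0.43 for GATA1 and -0.85 for P53 at 6 bases, and above 0 with UV, at 0.51 for both.

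GATA1 and P53 shared much of their response to UV outside their own sites. Of the 136 6-mers higher with GATA1 and the 174 higher with P53, 104 were higher with both, where 11.4 would be expected of independent lists, and 79 of these held AAA or TTT. Lower with both were 15, against 5.1 expected. These expected numbers treat 6-mers as independent, while overlapping 6-mers share probes, so the excess over them is descriptive only. None was higher with GATA1 and lower with P53, and 6 were the other way. The Spearman correlation of the changes across 6-mers was 0.630 and Pearson's r was 0.303, or 0.651 and 0.497 without the GATA core. The rank scores of the 2 proteins correlated at 0.403 without UV and at 0.790 with UV. No array was shared between the proteins, but they were used at different concentrations.

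Of the 9 sites of other transcription factors, 3 rose and 3 fell in rank score with GATA1, and 3 rose and 4 fell with P53. Among these sites the E-box CAGCTG fell most, at -0.18 and -0.21, beyond the -0.081 of WGATAR with GATA1, and TAATTA rose by 0.238 and 0.239. In log2 change, the homeodomain site TAATTA rose by 0.39 with GATA1 and by 0.43 with P53, the TATA box by 0.21 with GATA1 and was at 0.12 with P53, and the ETS site CCGGAAR rose by 0.17 with GATA1 and was at 0.05 with P53. The E-box CACGTG fell by 0.11 and 0.27, the E-box CAGCTG by 0.23 and 0.24, and the GC box by 0.19 and 0.16. The AP-1 site was at 0.10 with GATA1 and fell by 0.19 with P53, the RUNX site was at 0.05 and 0.04, and the CRE, with 6 probes, was at 0.03 and 0.01. In log2 change alone, the fall of the P53 decamer with P53, at -0.38, was not far beyond that of the E-box CACGTG. Against lists matched on signal the decamer lost less, at percentile 97.1, and CACGTG more, at percentile 0. The rank score changed by 0.033 for the decamer, with an interval that held 0, and by -0.13 for CACGTG.

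The designed sequences, with 8 spots each except for 3 with 16, held stronger P53 sites than the universal probes and were compared after the data had been seen. Without UV, the full site GCGGGCATGCCCGGGCATGCCCGCGC was 5.90 above the array's median on the log2 scale (SD 0.32), CTCAACATGTTGGGACATGTTCCTGC 5.41, CGCAGACATGCCCGGGCATGCCTCGC 5.13, CACGGGCATGTCTGGGCATGTCTCAC 5.12 and GCGGGCATGCCCGCGGGCATGCCCGC 4.32. Among the universal probes these sites stood at percentiles 99.976 to 99.998 without UV and 99.72 to 99.98 with UV. With UV they lay between 1.51 and 1.92 with 5 to 8 of their 8 spots at the highest scanner value, so the levels with UV are lower bounds and their falls upper bounds. GCGAGCATGCTCGAGCATGCTCGCGC was at 0.98 without UV and 0.85 with UV, with 0 spots at that value. The alternating probe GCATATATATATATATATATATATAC, with 0 dipyrimidine steps, went from -0.72 (SD 0.39) to 0.95 (SD 0.12) with P53, a change of 1.77 ± 0.14 (SE over spots), and changed by 0.46 with GATA1, where 4 of 8 spots were at the highest value with UV. The AC repeat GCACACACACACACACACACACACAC fell by 1.65 with P53 and by 1.02 with GATA1, and the CATG repeat GCATGCATGCATGCATGCATGCATGC by 2.04 and 2.21.

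**Figure D5:**
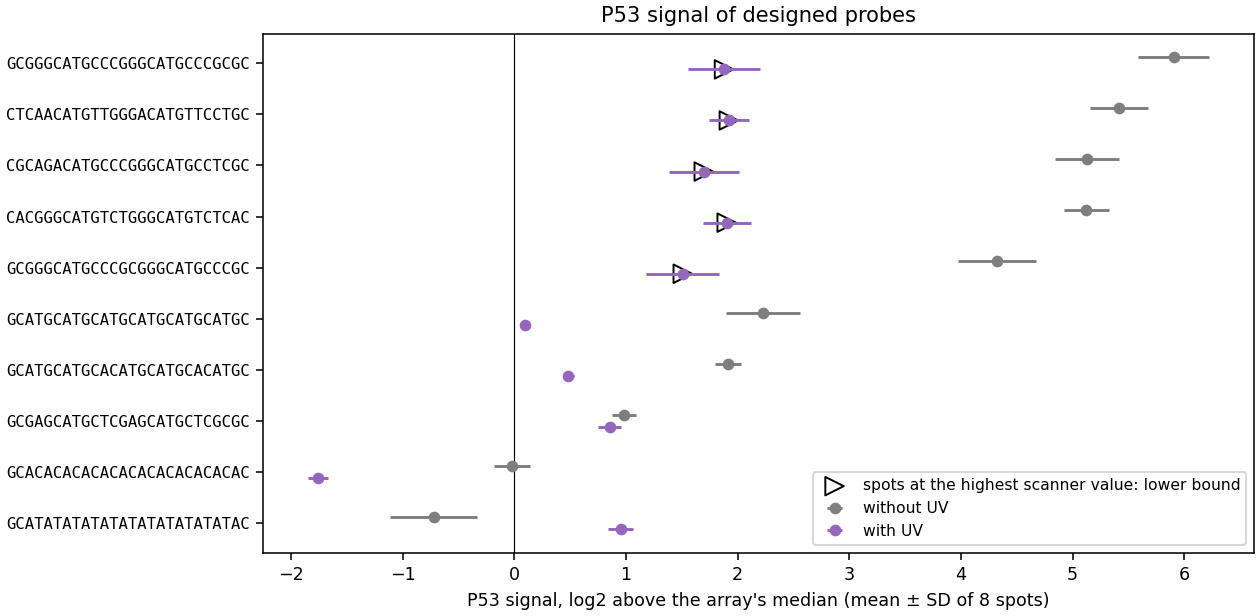
P53 signal of 10 designed sequences without UV and with UV, as log2 above the array's median, mean with SD over 8 spots; open triangles mark values with spots at the highest scanner value, which are lower bounds. The alternating AT sequence is the one that goes from below 0 to above it.

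A further 4 designed sequences came with 183 variants each, changed at 1 or 2 positions, and among them variants with added dipyrimidine steps stood higher on irradiated DNA against their original than variants without. Against GCACGCACATGCCCGGGCATGCGCGC, which was at 2.80 without UV and 0.72 with UV, the 88 variants with 2 added steps lay at a median of -0.22 with UV and the 79 with 0 added steps at -0.44. Without UV these medians were -1.58 and -1.92. In the other 3 families, whose originals hold 0 steps, 152 variants had 2 added steps and 31 had 0. Their medians with UV were 0.30 and -0.02 for GCACGCACATGTGTACACATGTGCGC, 0.37 and 0.24 for GCACGCACGTGTGTGTGTATGTGCGC and 0.15 and -0.15 for GCACGCGCATGTACGTGCATGTGCGC. Without UV they were -0.08 and -0.17, 0.26 and 0.34, and -0.11 and -0.11.

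As a UV change the families did not all point one way. Variants with 2 added steps changed by a median of -0.27, -0.34 and -0.14 in the 3 families without steps, and those with 0 added steps by -0.36, -0.50 and -0.34, but around GCACGCACATGCCCGGGCATGCGCGC the medians were -0.59 and -0.47, the other way round. The interquartile ranges of the 2 classes overlapped in each family. All spots lay below all spots of GCACGCACATGCCCGGGCATGCGCGC for 169 of its variants without UV and for 102 with UV. Variants entirely above their original numbered 26 without UV and 65 with UV for GCACGCACATGTGTACACATGTGCGC, 19 and 75 for GCACGCACGTGTGTGTGTATGTGCGC, and 20 and 42 for GCACGCGCATGTACGTGCATGTGCGC; spots also scattered less with UV, which makes such separation easier. GATA1 showed the same kind of gain, from 4 to 111, from 6 to 28 and from 13 to 95 in these families. The GATA1 change was also higher with 2 added steps than with 0 in all 4 families, so this difference was not particular to P53. A strict change of order, from entirely below the original to entirely above it, was seen for 2 variants, GCACGCACATGCCCGGGATTGCGCGC and GCACGCGCATGTAATTGCATGTGCGC. With GATA1 and UV both also stood above their original, at 0.61 against -0.57 and at -0.33 against -0.81.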

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

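Of the tests in this part, those on A and T content, on protein-free signal, on the strand of the run and on self-pairing probes were chosen only after the result was seen. Some results stood out because GATA1 and P53 moved in opposite directions at the same sites, and these differences between the proteins were not tested, since each rests on single arrays. They are given as the GATA1 change minus the P53 change on the log2 scale: WGATTR at -1.62, the P53 decamer RRRCWWGYYY at 0.53, its shorter form RRCWWGYY at 0.41, RCAAGY at 0.20 and the all-pyrimidine 6-mer at -0.10. Of these, WGATTR is close to the GATA1 site and the next 3 are P53 sites, so a difference between proteins has a place in the design, but the proteins also differed in concentration. None of the 5 kept opposite directions under both rescalings of the signal range. With quantile normalization the GATA1 and P53 changes were 0.0965 and 0.0712 for the decamer, -0.0875 and -0.13 for RRCWWGYY, -0.0925 and -0.21 for RCAAGY and 0.0218 and 0.0633 for the all-pyrimidine 6-mer, and as residuals of a linear fit those of WGATTR were 0.0351 and 0.15.

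Control spots, which no comparison used, did not all move one way with P53. The DarkCorner spots rose with P53 by 0.50 and the 3xSLv1 spots by 0.60 relative to the typical universal probe. Against the array's median they went from -0.185 and -0.34 without UV to 0.23 and 0.18 with UV. The ERCC (-0.50), E1A (-0.18), ETG (-0.89), DCP (-1.63) and GE_BrightCorner (-4.17) spots had medians below 0. With GATA1 the DarkCorner and 3xSLv1 spots fell by 1.78 and 1.85, from 2.91 and 3.01 above the array's median to 0.99 and 1.07. On the GATA1 array with UV, 25.7% and 17.5% of them were at the highest scanner value. Their sequences are not given in the sources used here, and no explanation was tested.

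The fall of WGATAR with GATA1 was weighed against the scanner's limit and against a signal common to all probes. With every spot at the scanner's highest value set to infinity, the median change was still -2.57 (interval -2.75 to -2.40), so such spots alone could not produce the fall. If UV added one constant signal to every probe, WGATAR probes would match other probes of equal signal without UV. The matched difference with UV was -0.35 (interval -0.39 to -0.26). The rule set beforehand asked for a difference beyond 0.3 with an interval that excludes 0. Both parts were met, so by that rule the test argued against one constant signal for the probes with matches. The bound was passed by less than the spread of the difference, however. The test was read as undecided only after its value was seen, because its interval reached inside the bound and 447 of 938 probes had matches. On this later reading, a common added signal may account for part of the fall of these 447 probes, while the others had too few matches to say. One constant keeps probes in order, however, and WGATAR lost its lead over the GATA core outside the consensus. Its rank score went from 0.474 to 0.393 (interval of the change -0.089 to -0.073) and that core's from 0.403 to 0.394. WGATAR as written on the listed strand went from 4.82 to 0.70 above the array's median, and its reverse complement from 3.55 to 0.90. Compared after seeing the data, these values argue against one constant as the whole of the fall. As part of it, such a signal cannot be told apart from a loss of GATA1 from its sites. An effect of UV lesions on GATA1 sites also stays open, since condition and array are the same factor.

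The rise of A and T runs with both proteins was weighed next. Uneven signal between the lower-numbered and higher-numbered rows of the slide was argued against. The smallest change of the TTTT run over these row groups, the proteins and the signal columns was 0.35 (interval 0.30 to 0.39). This test was set beforehand, left out after its value had been seen and then put back. The bound on its interval was first 0.1 and then 0.3, which left its reading as it was, and 0.3 was passed narrowly. Unevenness along the columns of the slide or on a finer scale was not examined. A and T content alone was argued against by the 6-mers ATATAT and TATATA, which hold 0 dipyrimidine steps and whose higher median was -0.083, although these are 2 6-mers. The designed alternating AT probe, with 0 steps as well, went the other way and rose by 1.77 with P53 and 0.46 with GATA1, so for longer stretches of A and T their content stays open. The strand of the run went with the pattern: for TTTT on the listed strand the higher of the 2 proteins' changes was 0.024, while AAAA there rose with both. A dim signal without UV was not the whole of the pattern, since the TTTT run was still at 0.307 with GATA1 and 0.361 with P53 as the residual of a linear fit, and at 0.466 and 0.57 with quantile normalization. A signal that does not come from the protein stays open, as 104 6-mers were higher with both proteins and no array without protein was analysed here. UV lesions at neighbouring thymines also stay open and were not tested apart from these.

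The rise of the alternating AT probe with P53 was weighed last. A stretch of 8 alternating A and T did not go with a rise, as the 13 universal probes with such a stretch were at -0.080 (interval -0.84 to 0.03). The designed probe holds a longer stretch, so this test cannot decide on an effect that needs more alternating bases. A probe that can pair with itself was argued against by the CATG repeat, which can also do so and changed by -2.04 with P53 and -2.21 with GATA1. Against the line fitted over universal probes it was at -0.59 with P53, so the narrower signal range does not account for its place, although this is a single probe that holds the P53 core. The length of the repeat and the amount of double-stranded DNA on the probe stay open, and no biological explanation was tested.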

How the results depend on the processing

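The alternatives without saturated spots, by rows of the slide, with the strands kept apart and with steps counted on the listed strand alone were chosen after seeing the data. No paired analysis was possible because each protein and condition had 1 array, and leaving out a replicate was impossible for the same reason. The counts that follow are of pairs of a result and an alternative, so a result enters once for each alternative it was run under. For the results that answer a comparison, 110 pairs kept their value within their spread, or their count within 1.5 times, 70 moved and 6 changed direction. For the single sites and 6-mers 517 pairs kept their value, 210 moved and 31 changed direction. Some pairs could not move: leaving out the centring keeps every correlation as it is, and a top 2% list keeps that between conditions. Unless a reason is given, the cause was not tested.

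Without centring, the shift of the whole array enters each change, so 100% of 6-mers were higher and 0% lower for both proteins, WGATAR was at 2.03 with GATA1 and the P53 decamer at 5.37 with P53.

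With quantile normalization, WGATAR was at -0.996 and the P53 decamer at 0.0712, and 9.33% of 6-mers were lower with P53. The correlation with steps was 0.291 for GATA1 and 0.479 for P53, and that between the proteins 0.785. With GATA1, AGATAT (0.24), CCCCCC (0.81), GCGATA (0.32), the GATA core outside the consensus (7.56e-05), RRCWWGYY (-0.0875), RCAAGY (-0.0925) and the all-pyrimidine 6-mer (0.0218) changed direction, and with P53 the CATG decamer (0.26).

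As the residual of a linear fit, 3.99% of 6-mers were higher and 2.88% lower with GATA1 and 5.43% higher with P53. WGATAR was at -0.21 and the P53 decamer at 0.29, the correlation with steps was 0.340 for GATA1, and that between the proteins 0.848. With GATA1 the direction changed for AGATAT (0.28), CCCCCC (0.53), GATAAC (0.13), GATATC (0.0151), GCGATA (0.33), AGATAG (0.02), the GATA core outside the consensus (0.21), WGATCR (0.0479), WGATTR (0.0351), RRRCWWGYYY (-0.0241), RRCWWGYY (-0.12), RCAAGY (-0.11) and the all-pyrimidine 6-mer (0.0557). With P53 it changed for CATGCC (0.082), CATGTC (0.19), CCCCCC (0.11), GGGGGA (0.14), the CATG decamer (0.41), RRCWWGYY (0.0112), RCATGY (0.0356) and the CCCC run (0.000215). These alternatives remove the compression of the signal range with UV by their construction.

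With only the probes brighter than the median probe, 10.1% of 6-mers were higher with GATA1 and 9.76% lower with P53. The correlation with steps was 0.170 for GATA1 and 0.156 for P53, and WGATAR was at -2.85 with a rank score change of -0.145. With P53, TTCC was at -0.0108 and the all-pyrimidine 6-mer at -0.22.

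With 7-mers, the correlation with steps was 0.187 for GATA1 and 0.405 for P53, that between conditions 0.663 for GATA1 and that between the proteins 0.564, and 6.07% were lower with P53. With 8-mers these values were 0.142, 0.321, 0.618, 0.446 and 5.98%, and 16.2% of the top P53 list was shared. With the E-score, the correlation between conditions was 0.716 for GATA1, and 15.4% of the top P53 list was shared.

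With the raw column, the rank score change of WGATAR was -0.151, 4.62% of 6-mers were lower with P53, the P53 correlation with steps was 0.407 and that between the proteins 0.562. In the 2 random parts of the probes the correlation between the proteins was 0.604 each, and in the second part that of P53 with steps was 0.420. With the 5′ part of the variable part alone, the correlation between conditions was 0.728 for GATA1 and 0.508 for P53, and 4.81% of 6-mers were lower with P53.

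With a size bound of 0.5, 1.06% of 6-mers were higher and 4.95% lower with GATA1, and 1.78% and 0.385% with P53, since fewer pass a stricter bound. With a pseudocount, 1.25% were higher with GATA1, and 2.12% higher and 0.721% lower with P53. With steps counted over the whole variable part, the correlations were 0.0859 and 0.171, and as the median over the 7 classes of equal G and C content 0.3001 and 0.514, with classes from 0.928 to -0.44 for GATA1 and from 0.965 to -0.13 for P53.

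Without saturated spots, WGATAR was at -3.02 with a rank score change of -0.0905. On the lower-numbered rows 4.57% of 6-mers were lower with P53 and the correlation with steps was 0.409. On the higher-numbered rows that of GATA1 was 0.187 and that between the proteins 0.581. With the strands kept apart, 10.6% of 6-mers were higher with GATA1, and 17.6% higher and 21.8% lower with P53. The correlation between conditions was then 0.673 for GATA1 and 0.605 for P53, and 63.9% and 32.7% of the top lists were shared. With pyrimidine steps of the listed strand alone the correlations were -0.25 for GATA1 and -0.59 for P53, and with purine steps 0.436 and 0.803. Signal over background could not be assessed, as no background column was used here.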

Other observations

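The orientation of the GATA site on the probe went with its signal, a comparison chosen only after the result was seen. With WGATAR as written on the listed strand, GATA1 probes changed by -4.04 (446 probes), from 4.82 above the array's median without UV to 0.70 with UV. With its reverse complement there they changed by -2.39 (491 probes), from 3.55 to 0.90. The change also differed with the base after the core, largely along with the signal without UV. GATAA was at -3.53, GATAG at -1.67, GATAT at -1.502 and GATAC at -0.74, from levels of 4.61, 2.53, 2.66 and 1.55. By rank score GATAA went from 0.483 to 0.432, GATAG from 0.41 to 0.347, GATAT from 0.409 to 0.426 and GATAC from 0.338 to 0.332.

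Many control spots were at the scanner's highest value with UV. Of the ERCC spots, 65.2% reached it on the GATA1 array and 28.8% on the P53 array.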
